A study of Chlamydomonas reinhardtii with 56 samples.

How the data were processed

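Chlamydomonas reinhardtii, a unicellular green alga with a single chloroplast and a pair of flagella, was sampled by the submitters over a day of 12 h of light and 12 h of darkness. Strain 6145c (CC-2895) was grown phototrophically in a bioreactor in HSM, a minimal salts medium, under red and blue light at 28 degrees C. Messenger RNA was selected by its poly-A tail from 5 µg of total RNA, and strand-specific paired-end libraries were sequenced. The 56 libraries cover 28 time points in each of 2 replicate time courses. Times are zeitgeber times (ZT), the hours since the lights came on. Samples fall hourly from ZT1 to ZT11 and from ZT15 to ZT24, and at intervals of 0.5 h from ZT11 to ZT15.

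Per the file headers, the first deposited table holds one raw count per library for each of 17737 loci, under locus identifiers of annotation version v5.3.1. Its unit is the count, with no normalization by the authors. The second deposited table holds RPKM values that the authors made from the counts, rounded to 1 decimal, and gives v5.5 identifiers beside the v5.3.1 ones. The RPKM columns named for replicate 1 and replicate 2 were identical at 28 of 28 time points. Among 831 loci with RPKM over 20 throughout, the SD of the log2 ratio of RPKM to counts was 0.00095 for the replicate 1 counts and 0.237 for the replicate 2 counts. Every comparison was therefore made on counts, and the RPKM values were not used further. Trimmomatic, STAR, HTSeq 0.5.4p3 and DESeq2 1.4.5 are named in the submitters' processing notes. The genome build, the settings of these tools, the strand setting of the counting and the treatment of reads that fit several loci are not given in the sources used here. Since the build of the counts is not stated, no chromosome coordinates are printed.

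Of the 17737 v5.5 identifiers, 17730 were found among the 17742 loci of the annotation used here, which holds 0 gene symbols apart from locus tags. Gene symbols, functions and list membership were therefore taken from 25 gene lists written from general knowledge, by locus identifier, before the data were examined. Neither deposited table nor the annotation pairs these symbols with the loci, so the locus identifier printed at the first mention of each gene is the identity that the files give, and the symbol beside it was not checked against a source. For 17 lists loci were given, and the 8 others (core histones, axoneme, cytosolic ribosomal proteins, plastid ribosomal proteins, mitochondrial respiratory chain, proteasome, autophagy, fatty acid and storage lipid synthesis) were not analysed here. Of 185 loci in the lists 184 were found and 182 passed the count filter. PFR1 (Cre11.g473950) was not in the tables, and NIT1 (Cre09.g410950) and NRT2A (Cre09.g410850) were below the filter. Counts of paralogs with near-identical sequence are uncertain, because the handling of shared reads is unknown. This holds for the LHCBM genes, LHCSR3.1 and LHCSR3.2, PSBS1 and PSBS2, the RBCS, TUA and TUB pairs, CAH4 and CAH5, CCP1 and CCP2, and HSP22E and HSP22F.

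Library totals ranged from 3815963 to 38160974 counts, with a median of 13621071. The ZT18 libraries of both time courses were nearly identical: the chi-square of their counts per degree of freedom was 0.0841, against 4.26 to 88.1 for the other 27 pairs. After the counts had been seen, this pair was averaged and treated as 1 library, where the plan had been to use all 56, so 55 libraries entered the fits. Loci were kept by edgeR's filterByExpr on all 56 libraries (at least 10 counts at the median depth in a group's worth of libraries, and 15 in total), which left 15546 and removed 2191. Counts were scaled by TMM, whose factors were 0.632 to 0.949 from ZT1 to ZT9 and 1.05 to 1.24 from ZT10 to ZT24.

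R 4.3.3 and edgeR 4.0.16 were used. A negative binomial model with 1 coefficient per time point was fitted with glmQLFit (trended dispersion, robust), with 27 residual degrees of freedom, and tested with the quasi-likelihood F test, 2-sided. P-values were adjusted by Benjamini-Hochberg over the 15546 loci, and a locus was called at an adjusted p under 0.05, with a further count of those changed by at least 2-fold. Tests covered any difference among the 28 time points and 5 contrasts: the 13 light time points (ZT1 to ZT12) against the 15 dark ones, ZT1 against ZT24 (labelled 23 h apart, so that reading it as lights on takes the day to repeat), ZT12.5 against ZT12, ZT13 against ZT12, and the 9 time points from ZT11 to ZT15 against the other 19. Changes are log2 with their standard error (the change over the square root of F), and levels are CPM (TMM-scaled counts relative to library size, by edgeR), averaged over the libraries. Contrasts over many time points are differences of mean log2 levels, so their sign can differ from that of the ratio of mean CPM. Where a time point of the lower side has 0 counts, the fitted change depends on the prior count, and mean levels are given beside it. The median log2 ratio of mean CPM is given beside the fitted median of a list where they differ by at least 1. Peak time was the time point with the highest mean log2 level (prior count 2), for called loci with at least a 2-fold range, and carries no test. The CPM printed with a peak is the highest mean CPM, which can fall at another time point.

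In the contrasts over many time points, a locus with 0 counts at a time point on its higher side has no usable test, because the log mean of that time point is unbounded and the F statistic falls to about 0. This was found after the results had been seen. It left 211 loci without a usable test for light against dark and 254 for the window, of which 145 and 117 had a fitted change of at least 2-fold. These loci stay in the adjustment with a p near 1 and count as not called, but are named below as having no usable test, and the counts called are to that extent low. None of the printed rises and falls comes from them. As an alternative added afterwards, a small count was added at such loci.

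Gene lists were tested with camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 and beside it with an estimated one, adjusted by Benjamini-Hochberg over the 17 lists and 5 contrasts. Genes to name were set by rule before the data were examined, as were the contrasts, the lists, the filter, the tests and most of the alternatives. The rule took, per contrast, the 6 listed genes with the largest rise and the 6 with the largest fall, called, changed the same way in each time course and with at least 10 CPM on the higher side. It further took the 3 members of each list with the smallest p, at most 2 loci without a symbol each way, and for the test over all time points the 10 listed genes with the largest range. Where all libraries of a side had 0 counts, a floor of 3 counts over that side gives a lower bound on the fold. Alternatives were DESeq2 1.42.0, DESeq2 size factors, total-count scaling, no filter and a stricter filter, an adjusted p under 0.01, a term for the time course, other weights or time points, fits of fewer libraries, and each library left out in turn with the dispersion trend of the full fit, where a lone library is taken to vary like the other time points.

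Because the labels name 2 replicate time courses, the libraries of a course are paired across time. Across 351 pairs of time points the correlation of course differences had a median of 0.0719 (-0.247 to 0.579), and 151 exceeded 0.1. Among 26 adjacent pairs, the kind that ZT12.5 against ZT12 compares, the median was 0.301 and 24 exceeded 0.1. A term for the course was therefore fitted as an alternative. It takes out a difference common to all time points, but not one shared only by neighbouring ones. Contrasts over many time points take neighbouring ones as independent, so their standard errors and p-values can be too small. The whole procedure was tested on simulated data with 15546 loci, of which 200 were changed. At 2-fold, 100% of 50 changed loci were called for light against dark, 98% for the window, 46% for lights on and 54% at each lights-off step. At 4-fold these were 100%, 100%, 94%, 92% at ZT12.5 and 96% at ZT13. With so few loci changed, the adjusted p was harder to pass than in the data, where many were called. These shares therefore need not hold for the data. False calls numbered 1 to 14 among 15346 unchanged loci per simulation. Simulated libraries were drawn independently, with 1 spread per locus at all time points. In the data, course differences correlate between neighbouring time points and nearly all loci change. The false calls therefore do not show the rate for the data. Camera called 1 of 1 changed list and 0 of 99 unchanged ones in the simulation of light against dark. The simulated loci were drawn independently, so these calls do not show how camera's preset correlation performs on lists of correlated genes. In the real lists, correlations estimated for light against dark ranged from -0.08 (gamete markers) to 0.936 (tubulins).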

Results

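The series measured transcript levels through the daily cycle of synchronized Chlamydomonas cultures, in 28 time points with 1 library per time course and 2 time courses. The 13 time points from ZT1 to ZT12 were in the light and the 15 from ZT12.5 to ZT24 in the dark. Sampling was denser, at intervals of 0.5 h, from ZT11 to ZT15. Library totals ranged from 3815963 to 38160974 counts (median 13621071). Each locus has 1 spread shared by all time points, with 2 libraries per time point. The median standard error was 0.070 on the log2 scale for light against dark and 0.27 for lights on. Across loci, the log2 difference between replicate libraries had an SD of 0.339 to 0.907 at time points other than ZT18, and 0.763 at ZT1. Standard errors at time points of larger spread, such as ZT1, can therefore be too small. In a time point with 0 counts in all libraries, transcripts below the floor of 3 counts were not detectable, and such floors cover counting error only.

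Libraries lay in the order of the day along the first components, which held 51.8% and 24.4% of the variance. For 35 of 54 libraries the nearest library of the other time course was that of the same time, and for 51 it lay within 1 h. Pairs of replicate libraries correlated across loci with r from 0.9616 to 0.9904 at 27 time points, where loci are not independent replicates. At ZT18 r was 0.9994, and the totals were 9741756 and 9832912 counts. The ZT18 pair was counted as 1 library below.

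**Figure D1:**
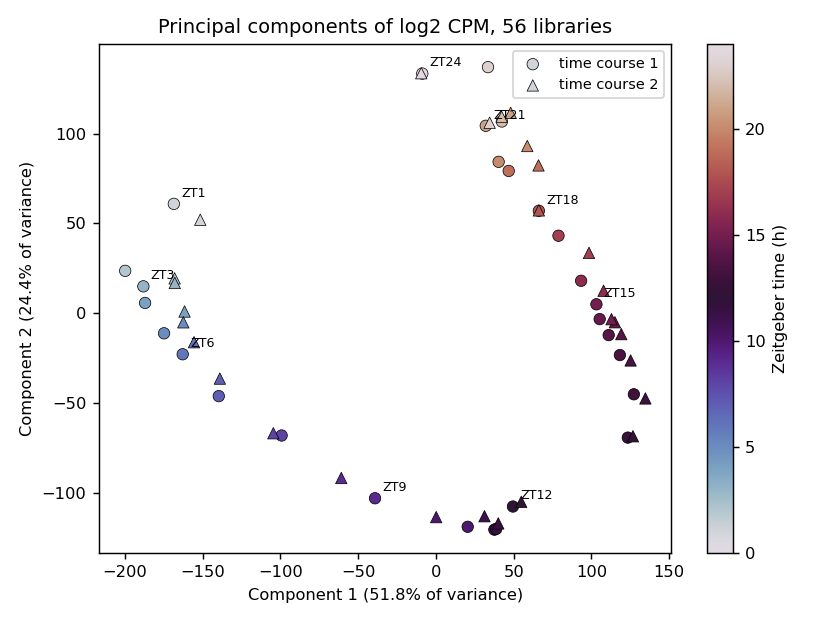
First and second principal components of log2 CPM for the 56 libraries, coloured by zeitgeber time (h), with circles for time course 1 and triangles for time course 2. Component 1 holds 51.8% and component 2 holds 24.4% of the variance, and libraries of the same time lie near each other.

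The first comparison asks which transcripts changed over the day and when each peaked. Nearly all did, and peak times differed between gene groups. Unless a course is named, peaks are those of the mean of both. Chaperone genes peaked early: 12 of 13 members of the heat shock list peaked from ZT1 to ZT3, and HSP90A (Cre09.g386750) peaked at ZT1 at 5435 CPM, with a lowest level of 19.7 CPM. HSP90A encodes a cytosolic chaperone. The tetrapyrrole and chlorophyll synthesis genes peaked from ZT1 to ZT8, 16 of 20 of them by ZT6. GSA1 (Cre03.g158000) peaked at ZT3 at 2395 CPM; it encodes the aminotransferase that forms the first tetrapyrrole precursor. Photosystem and electron transport genes had 20 of 22 peaks between ZT4 and ZT6, 21 in course 1 but 4 in course 2, where 15 lay from ZT7 to ZT9. The Calvin-Benson cycle of carbon fixation had 12 of 14 in the span from ZT4 to ZT6, 12 in course 1 and 9 in course 2. For example, PRK1 (Cre12.g554800) peaked at ZT6 at 7509 CPM; it encodes phosphoribulokinase. The antenna proteins that bind chlorophyll, the light-harvesting complex list, had 15 of 21 peaks from ZT7 to ZT9, 9 in course 1 and 19 in course 2. The median peak of the photosystem list was ZT5 in course 1 and ZT7 in course 2 and that of the light-harvesting list ZT6 and ZT7. In course 2, 7 photosystem genes and 2 light-harvesting genes peaked before ZT7, and the order of the lists was not tested. LHCBM1 (Cre01.g066917) peaked at ZT9 at 21850 CPM, and LHCA4 (Cre10.g452050) peaked at ZT7 at 6608 CPM. CAH1 (Cre04.g223100) peaked at ZT6 at 3013 CPM; it encodes a periplasmic carbonic anhydrase of the carbon-concentrating mechanism, whose list had 9 of 13 peaks from ZT4 to ZT6.

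Genes of cell division peaked around dusk. In the DNA replication list 7 of 8 peaked from ZT10 to ZT12, and MCM4 (Cre07.g316850) peaked at ZT12 at 233 CPM; it encodes a subunit of the replicative helicase. CYCB1 (Cre08.g370401) peaked at ZT13 at 142 CPM and CYCA1 (Cre03.g207900) peaked at ZT12.5 at 155 CPM, both mitotic cyclins, and 4 of 4 tubulin genes peaked at ZT12.5 or ZT13. Fermentation and hydrogenase genes peaked there too, 7 of 9 from ZT12.5 to ZT15. HYDA2 (Cre09.g396600) peaked at ZT13 at 194 CPM; it encodes an iron hydrogenase. In the dark the intraflagellar transport genes, whose products build flagella, peaked from ZT13.5 to ZT22 (ZT13 to ZT23 in course 1 and ZT13.5 to ZT21 in course 2), and IFT46 (Cre05.g241637) peaked at ZT13.5 at 238 CPM. At the end of the night 6 of 6 glyoxylate cycle and gluconeogenesis genes peaked at ZT23 or ZT24. In course 1 all 6 did so, but 2 in course 2, where the median peak was ZT22. ICL1 (Cre06.g282800), which encodes isocitrate lyase, peaked at ZT23 by mean log2 level, while its highest mean CPM, 4727, was at ZT24. Of the clock and photoreceptor list 6 of 9 peaked at ZT24, among them ROC15 (Cre09.g410450) at 295 CPM and ROC75 (Cre02.g083750) at 301 CPM, both transcription factors of the clock. Photoprotection genes peaked at ZT1 (3 of 5) or ZT6 (2 of 5), and LHCSR1 (Cre08.g365900) peaked at ZT1 at 1066 CPM; its product dissipates excess light energy. Starch genes spread from ZT1 to ZT24, with 7 of 11 peaks from ZT4 to ZT9, and nitrogen assimilation genes likewise spread. GSN1 (Cre13.g592200) peaked at ZT12.5 at 1008 CPM; it encodes a glutamate synthase. The cell-cycle regulator list peaked from ZT9 to ZT13. Of the pair of gamete and zygote markers, which stand for other cell types, GAS28 (Cre11.g481600) peaked at ZT13.5 at 388 CPM and GSM1 (Cre08.g375400) peaked at ZT8 at 4.9 CPM.

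Ranges were wide. LHCBM4 (Cre06.g283950) had 0 counts at ZT24 and 3365 CPM at ZT8, at least a 30000-fold range, and LHCSR1 ranged at least 3900-fold. Without a time point at 0, LHCBM3 (Cre04.g232104) ranged by 12.78 on the log2 scale and CAH1 by 14.08. Of loci without a symbol, Cre10.g452350 had a range of 13.04 on this scale, which includes a prior count, with a peak at ZT13. Median ranges were 67.4-fold for the Calvin-Benson cycle list and 17.1-fold for intraflagellar transport. They were 405-fold for tetrapyrrole synthesis, and 1510-fold for the light-harvesting complex, or 1110-fold by the ratio of mean CPM instead of the log2 level with a prior count.

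Of 15546 loci tested, 15360 (98.8%) changed over the 28 time points in the edgeR quasi-likelihood test at an adjusted p under 0.05 (Benjamini-Hochberg), and 186 did not pass. All 182 listed genes passed, the same number as adjusted over the list alone. By the mean of both time courses, at least a 2-fold range was seen in 15086 called loci and at least a 10-fold range in 6995. In both time courses taken alone, such ranges were seen in 15060 and 6622 called loci. A range within a course is that of single libraries, which their spread widens, and both courses use the same ZT18 value. The median range was 8.49-fold. By share of the 15086, 24.9% peaked from ZT1 to ZT3, 19.4% from ZT12.5 to ZT15 and 18.6% from ZT22 to ZT24, but 4.27% from ZT16 to ZT18. The span from ZT12.5 to ZT15 holds 6 time points and the other spans named here 3 each, so these shares do not compare as densities. The single time point ZT1 held 17% of peaks and 20.4% of troughs. Peaks in each time course alone lay within 1 h of each other for 69.5% of the loci, and 52.9% of all peaks fell in the light, or 42.6% with total-count scaling.

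**Figure D2:**
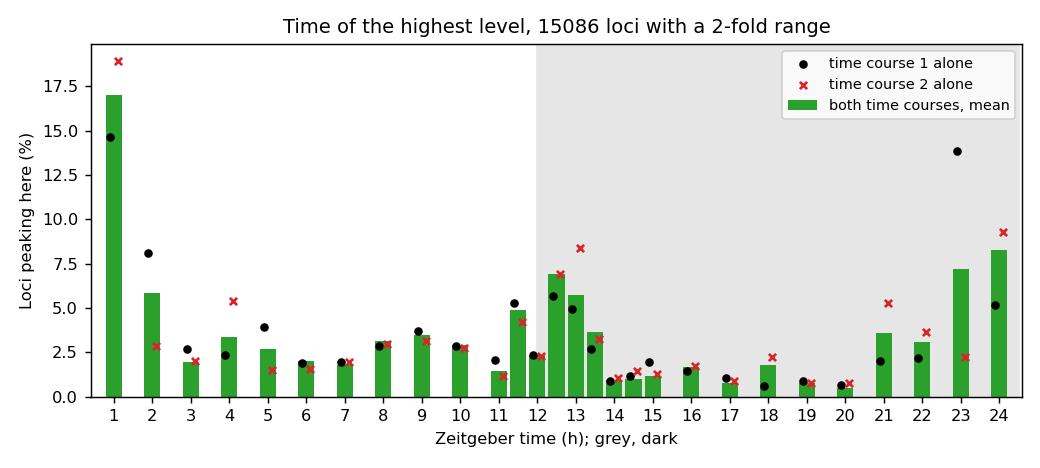
Share of 15086 loci (%) whose highest mean level fell at each time point (zeitgeber time in h, dark in grey), as bars for the mean of both time courses and as points for each alone. ZT1 holds 17% of the peaks, and the span from ZT16 to ZT18 holds 4.27%.

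**Figure D3:**
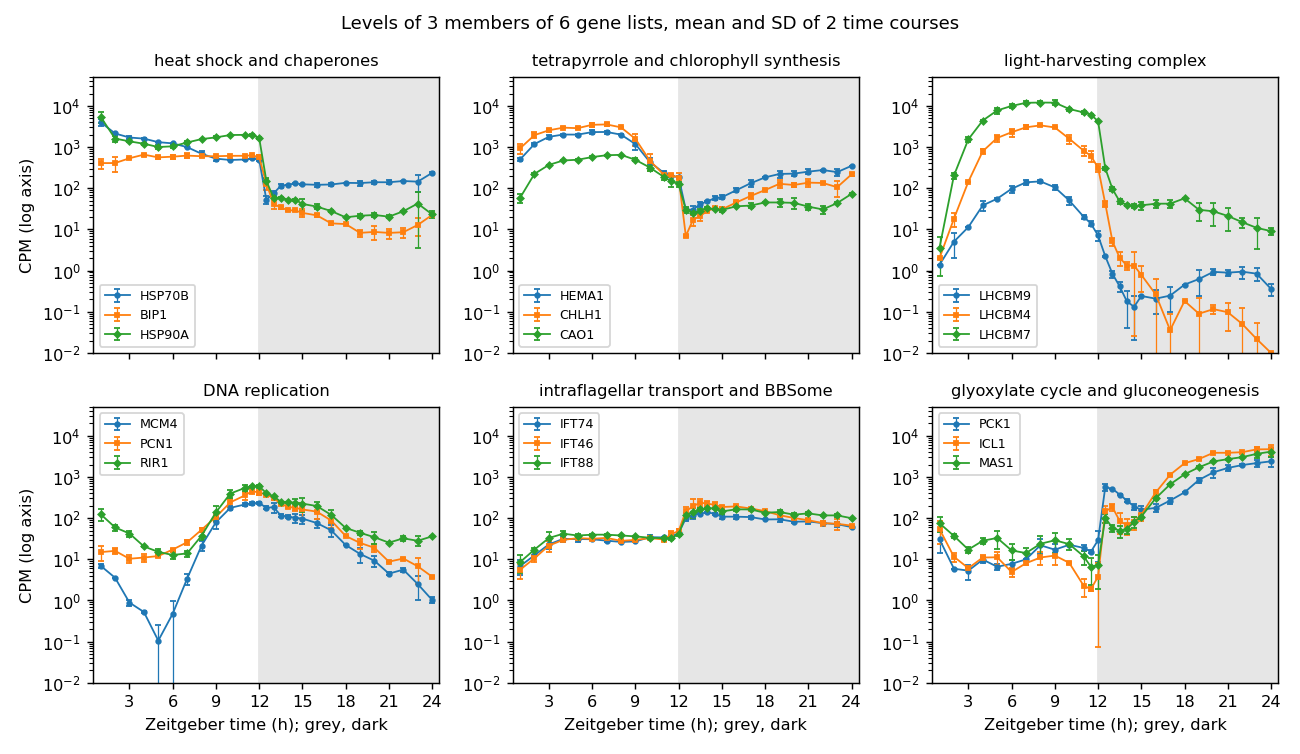
Levels (CPM, log axis) of 3 genes from each of 6 lists against zeitgeber time (h, dark in grey), as mean and SD of 2 time courses, with levels of 0 drawn at the lower limit and no SD at ZT18. HSP70B and HSP90A peak at ZT1, the light-harvesting genes at ZT8, the DNA replication genes at ZT11.5 or ZT12 and the glyoxylate cycle genes at ZT23 or ZT24.

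The next comparison set the light period against the dark period. Photosynthesis genes had higher transcript levels in the light. All 21 light-harvesting complex genes rose, with a median log2 change of 5.81 (camera adjusted p = 3e-10, adjusted p = 0.193 with an estimated correlation). Examples are LHCBM4 (10.64 ± 0.23, SE; 1357 against 3.58 CPM) and LHCA4 (8.90 ± 0.27, 3580 against 17.4 CPM), antenna proteins of photosystem II and photosystem I, although the LHCBM paralogs share sequence and their single counts are uncertain. All 20 tetrapyrrole and chlorophyll genes rose, median 3.98 (camera adjusted p = 1.48e-09, adjusted p = 0.24 with an estimated correlation), such as HEMA1 (Cre07.g342150) (3.01 ± 0.063, 1259 against 149.9 CPM), which encodes glutamyl-tRNA reductase, and CAO1 (Cre01.g043350) by 3.02 ± 0.062, chlorophyll a oxygenase. All 22 photosystem and electron transport genes rose, median 2.91 (camera adjusted p = 1.15e-08, adjusted p = 0.31 with an estimated correlation). Among them were PSBO (Cre09.g396213) by 4.31 ± 0.15, a subunit of the oxygen-evolving complex, and FNR1 (Cre11.g476750) by 3.66 ± 0.10, the reductase that forms NADPH. In the Calvin-Benson cycle 13 of 14 rose, median 2.71 (camera adjusted p = 6.93e-06, adjusted p = 0.299 with an estimated correlation), with PRK1 up by 4.53 ± 0.13 and PGK1 (Cre11.g467770), phosphoglycerate kinase, by 5.00 ± 0.17; 13 rose and 1 fell with total-count scaling.

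Carbon uptake, photoprotection and chaperone genes were higher in the light as well. In the carbon-concentrating list 10 of 13 rose, 2 fell and 1 had no usable test (camera adjusted p = 0.000164, adjusted p = 0.193 with an estimated correlation). CAH1 rose by 9.06 ± 0.26 (833 against 0.321 CPM), and LCIB (Cre10.g452800), a chloroplast protein of the same mechanism, by 3.45 ± 0.084. The gene without a usable test, LCI1 (Cre03.g162800), a bicarbonate transporter, peaked at ZT6, so its missing call says nothing of its level. In the photoprotection list 4 of 5 rose and 1, PSBS2 (Cre01.g016750), had no usable test, median 5.56 (by ratio of mean CPM 6.93) (camera adjusted p = 0.00993, adjusted p = 0.196 with an estimated correlation); LHCSR1 rose by 10.00 ± 0.23 (341 against 0.528 CPM). Of the heat shock and chaperone genes 12 of 13 rose, median 1.2 (by ratio of mean CPM 2.76) (camera adjusted p = 0.000246, adjusted p = 0.193 with an estimated correlation), with HSP90A up by 5.49 ± 0.12 and BIP1 (Cre02.g080700), a chaperone of the endoplasmic reticulum, by 4.85 ± 0.096; 9 rose and 2 fell with total-count scaling. Starch genes rose in 8 of 11 cases and fell in 1, median 1.09 (camera adjusted p = 0.00467, adjusted p = 0.199 with an estimated correlation), with STA2 (Cre17.g721500), the granule-bound starch synthase, up by 3.54 ± 0.064; 7 rose and 3 fell with total-count scaling.

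Genes for the use of stored carbon, for flagella and for hydrogen production were higher in the dark. All 6 glyoxylate cycle and gluconeogenesis genes fell in the light, median -3.69 (camera adjusted p = 0.00071, adjusted p = 0.199 with an estimated correlation): ICL1 changed by -6.52 ± 0.16 (11.2 against 1883 CPM) and PCK1 (Cre02.g141400), phosphoenolpyruvate carboxykinase, by -5.47 ± 0.12. All 10 intraflagellar transport genes fell, median -1.71 (camera adjusted p = 7.46e-05, adjusted p = 0.195 with an estimated correlation), including IFT46 (-2.40 ± 0.071) and IFT88 (Cre07.g335750) (-2.15 ± 0.059). Of 9 fermentation and hydrogenase genes 7 fell, 1 rose and 1 had no usable test, median -3.12 (by ratio of mean CPM -1.87) (camera adjusted p = 0.0268, adjusted p = 0.325 with an estimated correlation). HYDA2 fell most of these (-5.91 ± 0.10). With total-count scaling this list was no longer called, at an adjusted p of 0.107. Clock genes went both ways, 4 up and 4 down, while 2 rose and 6 fell with total-count scaling: ROC40 (Cre06.g275350) changed by -9.45 ± 0.45 (0.271 against 78.5 CPM, with 0 counts at 7 light time points) and ROC15 by -7.69 ± 0.16, while ROC75 had a fitted rise of 5.13 ± 0.16 (33.9 against 21.2 CPM, with 0 counts at 1 dark time point). Of these ROC75 was no longer called in a fit of all light libraries against all dark ones. The list's median of 0.056 and mean of -1.54 differ in sign, its median becomes negative with total-count scaling (-0.37), and camera did not call it (adjusted p = 0.9).

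Division genes peaked across the border of light and dark. Of 8 DNA replication genes 6 were lower and 1 higher in the light by mean log2 level; 0 rose and 7 fell with total-count scaling. Of the 6, MCM2 (Cre07.g338000), RIR1 (Cre12.g492950) and MCM4 had a higher mean level in the light (genes named after the values were seen), and the list's median log2 ratio of mean CPM was 0.16 against a fitted median of -1.02. For TOP2 (Cre01.g009250), topoisomerase II, with 0 counts at 1 light time point, mean levels were 56.7 against 79.4 CPM. MCM4 had a fitted change of -1.46 ± 0.13 but levels of 74.7 against 64.8 CPM, and its sign turned in the fit of all light against all dark libraries. Camera called neither DNA replication (adjusted p = 0.259) nor the cell-cycle regulators (adjusted p = 0.596), of which 4 rose and 5 fell (1 rose and 6 fell with total-count scaling). Nor did it call tubulins (3 of 4 fell; 0 rose and 4 fell with total-count scaling; adjusted p = 0.383), nitrogen assimilation (3 rose and 2 fell; 2 rose and 4 fell with total-count scaling; adjusted p = 0.685) or the gamete markers (1 rose and 1 fell, adjusted p = 0.964). Among those, GAS28 changed by -5.63 ± 0.20 and GSM1 by 2.65 ± 0.17. The nitrogen median of 0.041 becomes -0.39 with total-count scaling.

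Altogether 13723 of 15546 loci differed between light and dark in the edgeR quasi-likelihood test (adjusted p under 0.05, Benjamini-Hochberg), 6076 higher and 7647 lower in the light. At 2-fold these were 2735 and 3777. Adjusted over the list alone, counts were the same in all 17 lists. With an estimated correlation none of the 85 list results of the 5 contrasts passed, and the smallest adjusted p was 0.101. The share higher in the light was 44.3%, and 29.6% with total-count scaling (4154 higher, 9880 lower), which shifts the median change of all loci by -0.425. It shifts that at lights on by -0.544 and that of the window by 0.29, and DESeq2 size factors shift the window's by 0.109, so every count of higher and lower loci is relative to TMM. For 337 called loci (2.46%) the ratio of mean CPM has the other sign, and 211 loci had no usable test.

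The lights-on comparison took the first sample of the day, ZT1, against the last of the night, ZT24. By the labels ZT24 came 23 h after ZT1, so reading the difference as a response to lights on takes the next cycle to repeat this one, which was not tested. Chaperone and photoprotection genes rose. Of 13 chaperone genes, 11 rose, or 13 adjusted over the list alone, with a median of 4.09 (camera adjusted p = 2.65e-07, adjusted p = 0.101 with an estimated correlation). HSP90A rose by 7.87 ± 0.42 (5435 against 23.2 CPM), and HSP70A (Cre08.g372100), a cytosolic HSP70, by 5.94 ± 0.34 (6805 against 111 CPM). The small heat shock protein gene HSP22F (Cre14.g617400) (7.28 ± 0.51, 342 against 2.15 CPM) rose as well, a near-identical paralog of HSP22E (Cre14.g617450). All 5 photoprotection genes rose, median 5.55 (camera adjusted p = 0.00417, adjusted p = 0.193 with an estimated correlation): LHCSR1 by 7.68 ± 0.62 (1066 against 4.91 CPM), and PSBS2, with 0 counts at ZT24, was at least 201-fold higher. In the carbon-concentrating list 10 of 13 rose and 1 fell (camera adjusted p = 0.00417, adjusted p = 0.299 with an estimated correlation; 10 rose and 2 fell with total-count scaling). Rises include CCP2 (Cre04.g222750) (6.63 ± 0.38, 103 against 0.97 CPM) and LCIA (Cre06.g309000), a channel of the chloroplast envelope, by 7.23 ± 0.78.

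The photosynthesis lists were higher in part at ZT1. Light-harvesting genes rose in 15 of 21 cases and fell in 3, median 1.87 (camera adjusted p = 0.0196, adjusted p = 0.636 with an estimated correlation), such as LHCA4 (4.08 ± 0.65). Tetrapyrrole genes rose in 15 of 20 cases, median 1.45 (camera adjusted p = 0.00574, adjusted p = 0.596 with an estimated correlation), with CHLM (Cre12.g498550), a methyltransferase of chlorophyll synthesis, up by 4.42 ± 0.41; 11 rose and 2 fell with total-count scaling. Calvin-Benson genes rose in 12 of 14 (camera adjusted p = 0.0104, adjusted p = 0.577 with an estimated correlation), while 8 rose and 2 fell with total-count scaling. Photosystem genes rose in 14 of 22 (camera adjusted p = 0.0286, adjusted p = 0.713 with an estimated correlation), with FNR1 up by 2.18 ± 0.33, while 8 rose and 3 fell with total-count scaling and the median moved from 0.86 to 0.32. DNA replication genes rose in 7 of 8 (5 rose and 0 fell with total-count scaling), median 1.69, where camera gave an adjusted p of 0.0672 and, with total-count scaling, 0.0403. MCM4 was among those that rose (2.75 ± 0.45, 6.96 against 1.03 CPM).

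Other lists were lower at ZT1 or went both ways. All 6 glyoxylate cycle genes fell, median -5.97 (camera adjusted p = 2.91e-05, adjusted p = 0.193 with an estimated correlation): ICL1 changed by -6.43 ± 0.55 (53.9 against 4727 CPM) and MDH2 (Cre10.g423250), malate dehydrogenase, by -6.18 ± 0.30. All 10 intraflagellar transport genes fell, median -3.19 (camera adjusted p = 3.63e-06, adjusted p = 0.199 with an estimated correlation), with IFT122 (Cre01.g065822) at -3.86 ± 0.22. Of the fermentation genes 7 of 9 fell, median -4.25 (camera adjusted p = 0.00401, adjusted p = 0.299 with an estimated correlation), with HYDA2 at -7.87 ± 0.44 and HYDA1 (Cre03.g199800), the other iron hydrogenase, at -6.76 ± 0.49. Tubulin genes fell in 3 of 4, or 4 of 4 adjusted over the list alone (camera adjusted p = 0.134). In the clock list 6 fell and 3 rose, while 0 rose and 6 fell with total-count scaling (camera adjusted p = 0.106), with ROC40 at -9.48 ± 1.09 and CHR1 (Cre14.g611300), a channelrhodopsin, at -4.18 ± 0.28. Starch genes fell in 6 of 11 and rose in 2, while 2 rose and 9 fell with total-count scaling (adjusted p = 0.32): STA2 changed by 2.39 ± 0.21 and AMYB1 (Cre06.g307150), a beta-amylase, by -2.12 ± 0.20. Cell-cycle regulators rose in 5 of 9 and fell in 1, while 1 rose and 2 fell with total-count scaling (adjusted p = 0.394). Nitrogen genes rose in 3 of 6 and fell in 1, while 2 rose and 2 fell with total-count scaling (adjusted p = 0.389), with GSF1 (Cre12.g514050), a glutamate synthase, up by 2.15 ± 0.17. Neither gamete marker passed, while 0 rose and 1 fell with total-count scaling (adjusted p = 0.887). The medians of the nitrogen (0.26) and gamete (0.26) lists become -0.28 and -0.31 with total-count scaling.

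In the edgeR quasi-likelihood test 11003 of 15546 loci differed (adjusted p under 0.05, Benjamini-Hochberg), 5124 higher and 5879 lower at ZT1. At 2-fold these were 3787 and 4710. The share higher was 46.6%, and 31.4% with total-count scaling (3504 higher, 7666 lower). Apart from heat shock and tubulins, counts adjusted over the list alone were the same. For 181 called loci a time point was at 0, such as Cre17.g742150, at least 292-fold higher, and Cre09.g398100, at least 106-fold lower at ZT1.

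**Figure D4:**
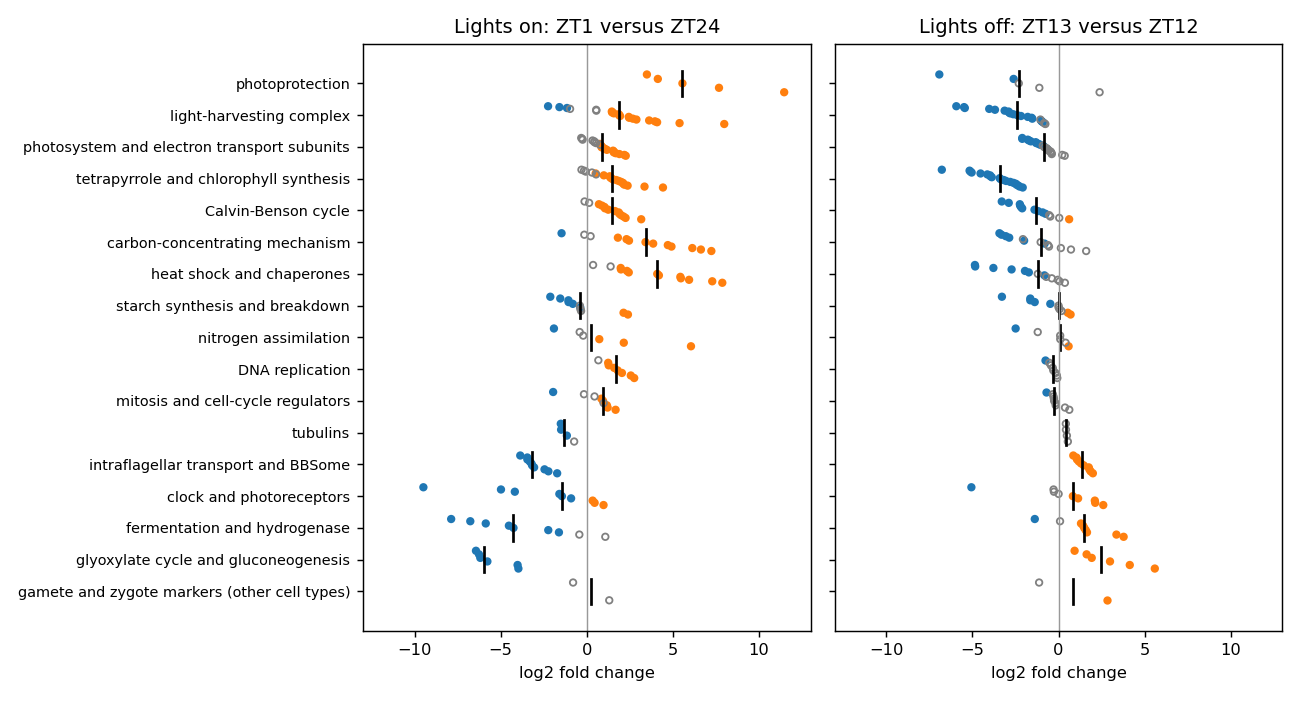
Log2 fold change of each list member at lights on (ZT1 versus ZT24) and lights off (ZT13 versus ZT12), with filled points for called members, open points for others and a bar at the list's median. Intraflagellar transport and glyoxylate cycle genes lie below 0 at lights on and above 0 at lights off, and the small medians of the nitrogen and gamete lists at lights on turn negative with total-count scaling.

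Lights off was followed with a pair of comparisons, ZT12.5 and ZT13 against ZT12. Both use the same ZT12 libraries, so their results are not independent of each other. Chlorophyll synthesis genes fell within the first 0.5 h. All 20 tetrapyrrole genes fell at ZT12.5, median -2.96 (camera adjusted p = 8.32e-11, adjusted p = 0.199 with an estimated correlation), and all 20 at ZT13, median -3.39 (camera adjusted p = 1.82e-11, adjusted p = 0.199 with an estimated correlation). CHLH1 (Cre07.g325500), a subunit of magnesium chelatase, changed by -4.72 ± 0.33 at ZT12.5 (6.89 against 182 CPM) and by -3.41 ± 0.30 at ZT13. GSA1 changed by -4.76 ± 0.90 and -6.77 ± 1.00. Light-harvesting genes fell in 7 of 21 cases at ZT12.5, or 6 adjusted over the list alone (median -0.98, camera adjusted p = 0.000629, adjusted p = 0.545 with an estimated correlation). At ZT13, 18 fell, or 20 adjusted over the list alone (median -2.40, camera adjusted p = 6.99e-08, adjusted p = 0.299 with an estimated correlation), with LHCBM4 at -5.93 ± 0.46 (5.11 against 317 CPM). Calvin-Benson genes fell in 8 of 14 at ZT12.5 (camera adjusted p = 0.00675, adjusted p = 0.575 with an estimated correlation). At ZT13, 10 fell and 1 rose (camera adjusted p = 0.000792, adjusted p = 0.469 with an estimated correlation), with RBCS1 (Cre02.g120100), a small subunit of Rubisco, at -3.29 ± 0.48. Photosystem genes fell in 1 of 22 at ZT12.5 (camera adjusted p = 0.265) and 11 at ZT13 (camera adjusted p = 0.00744, adjusted p = 0.636 with an estimated correlation).

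Chaperone and carbon-concentrating genes fell too. Of the heat shock list 7 of 13 fell at ZT12.5 (median -0.81, camera adjusted p = 6.72e-05, adjusted p = 0.182 with an estimated correlation) and 7 at ZT13, or 8 adjusted over the list alone (median -1.20, camera adjusted p = 6.02e-05, adjusted p = 0.182 with an estimated correlation). HSP70A changed by -4.33 ± 0.32 (89.7 against 1797 CPM) and -4.85 ± 0.33. Of the carbon-concentrating list 6 of 13 fell at each step (camera adjusted p = 0.00504, adjusted p = 0.299 with an estimated correlation; at ZT13 camera adjusted p = 0.0122, adjusted p = 0.344 with an estimated correlation), with LCIC (Cre06.g307500), a partner of LCIB, at -4.14 ± 0.29 and -3.06 ± 0.27. LHCSR1 changed by -5.71 ± 0.85 and -6.92 ± 0.85. The photoprotection list had 1 and 2 falls among 5 (camera adjusted p = 0.503 and 0.281), with medians of -0.88 and -1.11 where members at 0 are set to their bound.

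Genes of carbon remobilization, flagella and fermentation rose. All 6 glyoxylate cycle genes rose at ZT12.5, median 2.81 (camera adjusted p = 1.84e-07, adjusted p = 0.182 with an estimated correlation), and at ZT13, median 2.46 (camera adjusted p = 1.18e-05, adjusted p = 0.193 with an estimated correlation). ICL1 rose by 5.27 ± 0.55 (147 against 3.78 CPM) and 5.59 ± 0.55, PCK1 by 4.28 ± 0.39 and 4.14 ± 0.38. All 10 intraflagellar transport genes rose at ZT12.5, median 1.28 (camera adjusted p = 9.81e-08, adjusted p = 0.193 with an estimated correlation), and at ZT13, median 1.39 (camera adjusted p = 1.84e-07, adjusted p = 0.193 with an estimated correlation), with IFT88 up by 1.76 ± 0.21 at ZT13. Of 9 fermentation genes 7 rose and 1 fell at each step (median 1.81, camera adjusted p = 2.2e-05, adjusted p = 0.193 with an estimated correlation; at ZT13 1.49, camera adjusted p = 0.000656, adjusted p = 0.23 with an estimated correlation), and HYDA2 rose by 2.78 ± 0.27 and 3.36 ± 0.28.

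Other lists moved less or both ways. Clock genes rose in 4 of 9 at ZT12.5 and fell in 1, or 3 adjusted over the list alone (camera adjusted p = 0.31, with a median of 0.54 and a mean of -0.027). At ZT13, 5 rose and 1 fell (adjusted p = 0.12), with CHR1 up by 2.13 ± 0.25 and ROC75 at -5.06 ± 0.72. Starch genes fell in 5 of 11 at ZT12.5 and 5 at ZT13, where 2 rose (camera adjusted p = 0.056 and 0.0778, and 0.0495 at ZT12.5 with total-count scaling). Their medians were 0.025 and 0.00086 and their means -0.62 and -0.63. STA2 changed by -3.29 ± 0.22 at ZT13. Replication, cell-cycle and tubulin genes were near their peak on both sides of dusk. DNA replication genes had 0 calls in 8 at ZT12.5 and 1 fall at ZT13, or 0 adjusted over the list alone (camera adjusted p = 0.512 and 0.393). Cell-cycle regulators had 1 fall in 9 at each (adjusted p = 0.926 and 0.564), and tubulins 0 calls in 4 (adjusted p = 0.332 and 0.389). Of 6 nitrogen genes 1 fell at ZT12.5, and 1 fell and 1 rose at ZT13 (adjusted p = 0.402 and 0.685, the latter with a median of 0.098 and a mean of -0.42). GSF1 changed by -2.49 ± 0.17 at ZT13. Of the gamete markers 1 rose and 0 fell at each step. GAS28 rose by 2.83 ± 0.56 at ZT13 and GSM1 changed by -1.13 ± 0.54, a fall only as adjusted over the list alone (camera adjusted p = 0.698 and 0.512).

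In the edgeR quasi-likelihood test (adjusted p under 0.05, Benjamini-Hochberg) 5759 of 15546 loci differed at ZT12.5, 2520 higher and 3239 lower than at ZT12. At ZT13, 6658 differed, 3204 higher and 3454 lower. At 2-fold the counts were 1354 and 1579, then 1786 and 1728. The 6658 at ZT13 rest on a spread per locus shared by all time points. From the 4 libraries of ZT12 and ZT13 alone 4131 were called, and 6637 from those of ZT12 and ZT12.5. Leaving out any 1 of the compared libraries lowered the counts of higher loci at both steps, most without ZT12 replicate 1. Such fits leave 1 library at a time point, so the lower counts do not show the weight of that library alone.

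The last comparison set the 9 densely sampled time points from ZT11 to ZT15, around dusk, against the other 19. Cell division genes were higher in this window. All 8 DNA replication genes rose, median 4.02 (by ratio of mean CPM 2.67) (camera adjusted p = 4.22e-05, adjusted p = 0.193 with an estimated correlation), with TOP2 up by 5.42 ± 0.16 (172 against 20.2 CPM) and MCM4 by 4.70 ± 0.10 (163 against 25.2 CPM). All 9 cell-cycle regulators rose, median 1.21 (camera adjusted p = 0.00071, adjusted p = 0.199 with an estimated correlation), among them CYCB1 (5.16 ± 0.13, 96.4 against 13.9 CPM), the cyclin-dependent kinase gene CDKB1 (Cre08.g372550) (5.13 ± 0.14, 139 against 16.8 CPM) and WEE1 (Cre07.g355250), a kinase that restrains mitotic entry (4.64 ± 0.12). All 4 tubulin genes rose, median 1.66 (camera adjusted p = 0.0146, adjusted p = 0.365 with an estimated correlation), such as TUB1 (Cre12.g542250) (2.12 ± 0.092, 1521 against 402 CPM), although members of each tubulin pair share near-identical sequence. Of 9 fermentation genes 8 rose, median 2.62 (by ratio of mean CPM 1.16) (camera adjusted p = 0.000593, adjusted p = 0.195 with an estimated correlation), including ACK1 (Cre09.g396700), acetate kinase, by 3.33 ± 0.095 (77.4 against 18.3 CPM). Of 10 intraflagellar transport genes 8 rose (10 rose and 0 fell with total-count scaling), median 0.42 (camera adjusted p = 0.0346, adjusted p = 0.566 with an estimated correlation), with IFT46 up by 1.28 ± 0.068.

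Photosynthesis genes were lower in the window. All 20 tetrapyrrole genes fell, median -3.94 (camera adjusted p = 7.09e-10, adjusted p = 0.23 with an estimated correlation), with CHLD (Cre05.g242000), a subunit of magnesium chelatase, at -6.09 ± 0.21 (4.39 against 508 CPM) and UROD1 (Cre11.g467700), uroporphyrinogen decarboxylase, at -5.68 ± 0.19. Calvin-Benson genes fell in 12 of 14, median -2.35 (camera adjusted p = 3.23e-05, adjusted p = 0.333 with an estimated correlation), with RCA1 (Cre04.g229300), Rubisco activase, at -3.28 ± 0.095; 2 rose and 11 fell with total-count scaling. In the carbon-concentrating list 10 of 13 fell and 3 had no usable test, median -1.83 (by ratio of mean CPM -3.66) (camera adjusted p = 2.54e-05, adjusted p = 0.193 with an estimated correlation), with LCIB at -3.65 ± 0.091 (74.6 against 1466 CPM). Photosystem genes fell in 15 of 22 and had fitted rises in 2, PSAE (Cre10.g420350) and PCY1 (Cre03.g182551), whose mean levels were lower in the window (camera adjusted p = 0.00369, adjusted p = 0.618 with an estimated correlation); 4 rose and 14 fell with total-count scaling. Heat shock genes fell in 10 of 13 (camera adjusted p = 0.0122, adjusted p = 0.24 with an estimated correlation), while 2 rose and 8 fell with total-count scaling. Starch genes fell in 8 of 11, with 3 rises (camera adjusted p = 0.0315, adjusted p = 0.31 with an estimated correlation; 4 rose and 7 fell with total-count scaling). Photoprotection genes fell in 2 of 5 and 3 had no usable test, median -3.04 (by ratio of mean CPM -5.51) (camera adjusted p = 0.0428, adjusted p = 0.299 with an estimated correlation). Light-harvesting genes had 13 falls and 4 fitted rises, median -0.58 (by ratio of mean CPM -1.91), while 8 rose and 12 fell with total-count scaling (camera adjusted p = 0.178, and 0.0495 with total-count scaling). All 4 fitted rises, in LHCBM1, LHCBM4, LHCBM5 (Cre03.g156900) and LHCBM8 (Cre06.g284250), go with a lower mean level in the window. LHCBM1 had a fitted change of 2.02 ± 0.15 with 5262 against 6737 CPM, and -2.23 against ZT4 to ZT8 alone. Clock genes had 5 falls, 3 fitted rises with a lower mean level in the window (ROC15, ROC40 and CPH1 (Cre06.g295200)) and 1 without a usable test, ROC75 (camera adjusted p = 0.0751, and 0.0226 with total-count scaling). PHOT1 (Cre03.g199000), a blue light receptor, changed by -1.13 ± 0.042.

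Of the glyoxylate cycle genes 3 fell, and 3 had fitted rises with a lower mean level in the window (PCK1, CIS2 (Cre03.g149100) and MDH2; median -0.80 (by ratio of mean CPM -1.93); camera adjusted p = 0.416). ICL1 at -2.21 ± 0.15 and MAS1 (Cre03.g144807), malate synthase, at -2.44 ± 0.14 were lower than at the other times, but higher than at ZT4 to ZT8 alone, by 1.80 and 0.68. Nitrogen genes had 2 rises, 3 falls and 1 without a usable test (adjusted p = 0.31), with GSN1 up by 3.91 ± 0.14. Of the gamete markers GAS28 rose by 2.67 ± 0.18 (list adjusted p = 0.685). GSM1, at -0.44 ± 0.20 and under 5 CPM throughout, was called as lower here but not with DESeq2, with its size factors or with total-count scaling.

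In the edgeR quasi-likelihood test 13056 of 15546 loci differed (adjusted p under 0.05, Benjamini-Hochberg), 6712 higher and 6344 lower in the window. At 2-fold these were 3053 and 1674. Adjusted over the list alone, counts were the same in all 17 lists. The share higher was 51.4%, and 67.3% with total-count scaling (8699 higher, 4219 lower). Genes named here for a sign that turns by mean level were chosen after their values were seen. For 419 called loci (3.21%) the ratio of mean CPM has the other sign, and 254 loci had no usable test.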

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

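Alternatives that leave out ZT18 or ZT23, count both ZT18 libraries or add a small count at loci with a time point at 0 were chosen after the data had been seen, and the others were planned. With both ZT18 libraries counted, or with ZT18 or ZT23 left out, 293 of 293 results for named genes kept their direction and side of the threshold. With a small count added at loci with a time point at 0, light against dark called 13780 loci with edgeR's default prior count and 13829 with a larger one. The window called 13077 and 13149, and 121 of 121 named results kept direction and side each time. A term for the time course left 85 of 85 list results and 292 of 293 gene results on their side, and PSBR (Cre06.g261000) at ZT12.5 passed with it. DESeq2 kept 291 of 293. With an estimated correlation 50 list calls were lost and 35 results were as before. Total-count scaling kept 80 of 85 list results and 287 of 293 gene results, but moved the window's lower loci to 4219 and the share of peaks in the light to 42.6%. An adjusted p under 0.01 kept 287 of 293 gene results and lost the call of 6. A cosine of 24 h gave 44.7% of peaks in the light. From only the 4 libraries of ZT12 and ZT13, 4131 loci were called, 1981 higher and 2150 lower, where fewer residual degrees of freedom are part of the setting. With equally few, 6637 were called at ZT12.5, more than the 5759 of the fit of all libraries, and 9649 at lights on. Across loci, the log2 difference between replicate libraries had an SD of 0.553 at ZT13, 0.387 at ZT12 and 0.37 at ZT12.5. The fit of all libraries gives all time points 1 spread per locus, which can be too small at ZT13. Over the single steps such fits of 4 libraries kept 161 gene results, lost the call of 4 and called 7 others. The fit of all light against all dark libraries called 11003 loci, 5465 higher and 5538 lower, where the spread over the day is part of the error. It kept 52 of 59 gene results and lost the calls of TOP2, MCM3 (Cre06.g295700), ROC75, CDKB1, GSN1 and TUA1 (Cre03.g190950). Signs reversed for TUA1 in light against dark without ZT11 to ZT15 (0.010) and for MCM4 in the fit of all light against all dark libraries (0.17). Against ZT4 to ZT8 alone the window gave 0.68 for MAS1, 1.80 for ICL1 and -2.23 for LHCBM1. For these moved and reversed values the cause was not tested. Leaving out 1 library at a time gave 15330 to 15394 loci changing over the day, and 15042 to 15144 at 2-fold. It gave 13586 to 13766 loci for light against dark (5786 to 6114 higher, 7562 to 7925 lower), 9842 to 10472 at lights on (4367 to 5025 higher, 5437 to 5475 lower) and 12911 to 13129 for the window (6541 to 6789 higher, 6203 to 6498 lower). Lights off gave 4063 to 4772 at ZT12.5 (1615 to 2091 higher, 2386 to 2681 lower) and 4838 to 6424 at ZT13 (2130 to 3059 higher, 2708 to 3365 lower), the lowest counts of higher loci without ZT12 replicate 1. Of 7343 gene results so obtained 7301 kept direction and side, 39 were no longer past the threshold and 3 newly passed. Some of those lost, such as LHCSR3.2 (Cre08.g367400) without ZT12 replicate 2 in light against dark, had a time point at 0 once the library was gone, and so no usable test. The planned limma fits of RPKM values with pseudocounts of 1 and 0.1 were not run, because identical replicate columns leave no replicate spread. Depth limits loci near 0 counts, where a fold is a bound or a test is unusable. At the single steps a 2-fold change was called in about 46 to 54% of simulated cases. Few loci were changed there, so the adjusted p was harder to pass than in the data, and this share need not hold for them.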

Other observations

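The tests of the ZT18 libraries and the runs of 9 consecutive time points were chosen only after the result was seen. The runs of 13 consecutive time points were chosen after the principal components had been seen, and the random splits and the overlap of lights on and lights off were set before their results were seen.

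Some listed genes differed between the 2 time courses. The genes named here were chosen after the values were seen, and no list was tested for this difference. The test below takes the time points of a course as replicates, though only 2 courses exist. Course differences at adjacent time points correlate (median 0.301). The standard errors and p-values can therefore be too small, and they do not speak for further cultures. In the edgeR quasi-likelihood test with a term for the course (Benjamini-Hochberg), CAH1 was higher in course 2 by 0.93 ± 0.15 on the log2 scale (adjusted p = 9e-05), and LCI1, a bicarbonate transporter, by 0.76 ± 0.14 (adjusted p = 0.000337). DHC1B (Cre06.g250300), the motor of retrograde flagellar transport, was higher by 0.39 ± 0.070 (adjusted p = 0.000253), and the small heat shock gene HSP22C (Cre03.g145787) by 0.82 ± 0.20 (adjusted p = 0.00417). CRD1 (Cre07.g346050), an enzyme of chlorophyll synthesis, was lower, at -0.23 ± 0.045 (adjusted p = 0.000487). Of 182 listed genes 33 differed, 0 of them by 2-fold. Of all 15546 loci 3814 differed, 2541 higher and 1273 lower in course 2, 17 of them by 2-fold, with a median size of 0.22. Peaks at ZT23 numbered 2087 of 15086 in course 1 and 342 in course 2. The ZT23 libraries of both courses correlated across loci with r = 0.9687. In the other course, the library nearest to ZT23 was ZT24 for course 1 and ZT21 for course 2. Whether the difference in peaks belongs to the courses or to these single libraries was not told apart.

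Genes called at both lights on and lights off (ZT13) mostly went opposite ways. This held for 10 of 10 intraflagellar transport genes, 15 of 15 tetrapyrrole genes, 9 of 9 Calvin-Benson genes, 7 of 7 heat shock genes, 6 of 6 glyoxylate cycle genes and 6 of 6 fermentation genes. It also held for 12 of 15 light-harvesting genes, but for 2 of 5 starch genes. Of 5463 loci called in both, 5030 (92.1%) went opposite ways and 433 the same way. Chance overlap of the responses was tested by the loci that rose at lights on and fell at lights off, which numbered 2570 against 1138 for independent lists, a ratio of 2.26. No library is shared by both contrasts, so the overlap does not come from a shared library. The number for independent lists takes loci as independent, but loci change together, and no other pair of steps was compared. The ratio therefore argues against chance overlap only for loci that change independently of each other. That the same genes respond to light in both directions stays a hypothesis, since ZT24 was sampled 23 h after ZT1 by label. A cycle of 24 h without any response to light was not told apart from it here.

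The ZT18 libraries of both courses differed by less than sampling noise, with a chi-square per degree of freedom of 0.0841, where independent cultures gave 4.26 or more. A value under 1 is consistent with one library deposited under both courses, although the counts were not identical. That the shared library belongs to the second course is argued against: its mean distance to ZT17 and ZT19 was 0.087 larger for the second course than for the first. The same difference had a median of -0.111 over 23 other libraries of the second course, with 0.0164 as the highest. Whether it came from the first course stays open, and no biological explanation was tested.

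With 100 splits of the 28 time points each, the real one included, 1 of 100 called as many loci as light against dark (13723, highest other 12491) and 1 of 100 as many as the window (13056, highest other 12946). Neither rank says whether chance can be excluded, because many runs of neighbouring time points outrank all the other random splits. Of the 27 other runs of 13 consecutive time points 27 called more than 12491 loci (12565 to 13574), and of the 27 other runs of 9 time points 15 called more than 12946. Among the 28 runs of 13, which also differ in hours covered, light against dark called the most, at 2-fold 6512 against 6112 for the next. That next run goes from ZT24 to ZT11.5 and so covers nearly all of the light period. Among the 28 runs of 9, which differ in hours covered, 9 called at least as many loci as the window, the window included, and 15 did so at 2-fold, where the highest was 6589 against 4727.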
